A study of Oryza sativa with 12 samples.

How the data were processed

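The samples were leaves of FR13A and Goda Heenati seedlings, submerged for 3 d in water 70 cm deep or kept as non-submerged controls, with groups and replicate numbers 1 to 3 taken from the sample titles. Per the file headers and the submitters' processing notes, the authors scanned 12 one-colour (Cy3) Agilent rice arrays and read spot intensity with Agilent Feature Extraction 10.5.1.1. The deposited spot values are intensity on a linear scale, and the processed signal already had the background removed per the file headers. The authors' deposited value table holds log2 values for 42475 probes. Its columns had the same median, 10.02, and differed by at most 0.00136 at any rank, the single distribution that quantile normalization gives. Each correlated with its own array's log2 processed signal at r of at least 0.9975. The step itself is not given in the sources used here. It served as an alternative.

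Each array carries 45151 spots. Control spots, 59 further probes that the array names as controls, and spots flagged as outliers were left out, which left 42418 probes. The log2 processed signal had the array's 75th percentile subtracted, and spots of a probe were averaged. A probe was kept if it was well above background on all arrays of at least 1 group (33071 probes), and the probe with the highest mean stood for its gene. This gave 22744 genes, 22590 with a locus and 154 probes without one that were kept as genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in one fit of 4 group means with 8 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05 and at least 2-fold. Where no array of a group was well above background, a fold is a bound, written as at least N-fold. It sets the brighter group's mean against the mean, over the dim group's arrays, of the higher of the array's lowest signal well above background and the probe's own signal. Such a bound makes no allowance for sampling error, so single arrays, other probes or other processing can give a smaller fold.

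The array files identify genes by locus and the reference gene table used here (ASM3414082v1) holds no such locus, so neither pairs loci with names. The names printed come from 75 pairs of name and locus written from general knowledge before the data were examined. The table held 52 of these names on the chromosome of the locus, did not hold 22, and placed 1 on another chromosome, which was dropped. Sharing a chromosome does not establish that a name belongs to a locus, and each name should be read together with its locus. Of 37 gene lists planned, 17 had such loci. The other 20 were to be filled from product descriptions, which the table lacks, and were not analysed here. Pairs recalled later were not used. The rule for named genes took, from each list with a called member in a comparison, up to 3 members with the smallest adjusted p, and a fixed set whatever their values. LDH in Goda Heenati, and ACO1 and GA2ox1 for the difference between the responses, fall outside it and were chosen after their values were seen. Rankings over all genes with a name, also planned, could not be made without names, and at most 2 unnamed loci in each direction are printed. One called gene of the lists is not reported here. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over 25 tests of 5 lists in 5 comparisons, with an estimated correlation and fry beside it.

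The spot handling was tested on a small made-up set of spots. The fit and the set test were tested on simulated data made from the real genes' means and spreads. That simulation was written after the comparisons had first been run once on the real arrays, and the counts of calls were the same afterwards. Of 67 genes changed by 2 on the log2 scale, 40 (59.7%) were recovered for FR13A submerged against control and 25 (37.3%) for the difference between the responses, over 22182 genes. At a change of 1.5 the share for the difference was 19.4%. No call was in the wrong direction, and at most 11 unchanged genes were called in a comparison. For these shares the simulated arrays varied independently, without the deviations that real arrays of a slide share. Far fewer genes were changed than the submergence comparisons called. The shares and false calls therefore need not hold for the real arrays.

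The 3 slides each held 1 array of every group, and the slide number equals the replicate number. Slide 1 was scanned on another day and had 1837 to 2406 saturated probes per array, while the other slides had 0. Saturated spots were kept, which can shrink the fold changes of bright genes. Whether the numbers pair the samples was decided before any blocked fit was made. All 18 same-numbered pairs of arrays deviated together from their group means, with correlations from 0.261 to 0.787, against -0.552 to 0.031 for other numbers. The numbers coincide with the slides, so a slide effect and a batch of plants or RNA shared by a number cannot be told apart. Each slide holds 1 array of a group, so a slide on its own gives differences and no test. Alternatives covered background correction, normalization, the filter on dim probes, flags, several probes of a gene, the value table, the threshold, the groups in the fit, moderation, the replicate block, the scan day, array weights and leaving out each array. The normexp alternative used the median signal of a spot. Its estimate failed on FR13A submerged replicate 2, an array that enters every normexp value of submerged FR13A. Through the estimate of spread that all groups share, this array also enters the normexp p-values of every other comparison.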

Results

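Leaf transcripts of 2 rice (Oryza sativa) genotypes, FR13A and Goda Heenati, were measured after 3 d of complete submergence and in controls kept in a tank without water. The seedlings were 14 d old. Each sample pooled the leaves of about 20 plants, and each genotype and treatment had 3 biological replicates, which gave 12 one-colour arrays in 4 groups. Between 30643 and 34291 of 42418 probes lay well above background on an array. After selection 22744 genes were tested. Values are log2 processed signal relative to the array's 75th percentile, and fold changes are given on the log2 scale with the standard error (SE) of the limma fit, over 3 arrays per group. The number of arrays limits the precision of every comparison. Within a group, arrays correlated with r from 0.938 to 0.968 across genes, which are not independent replicates. Gene names are given with the locus to which they were assigned, since neither the array files nor the gene table used here pairs them.

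The first comparison asked which transcripts differed between submerged and control leaves of FR13A. Genes of fermentation, of gibberellin synthesis and signalling and of sucrose and starch breakdown were among those that rose. ADH2 (Os11g0210500), an alcohol dehydrogenase, was not well above background on any of the 3 control arrays and was well above it on all 3 submerged arrays, at least 1860-fold higher (limma adjusted p = 2.14e-06). That bound is for its brightest probe, and the log2 fold change was 8.30 at the lowest of its 3 probes and 8.10 with normexp background correction. ALDH2A (Os02g0730000), an aldehyde dehydrogenase, rose by 6.97 ± 0.43 (adjusted p = 5.4e-06), from a level of -3.82 ± 0.54 to 3.15 ± 0.84 (SD, n = 3 each, limma). In all, 4957 genes were called at an adjusted p under 0.05 and at least 2-fold, of which 2275 were higher and 2682 lower under submergence. The balance between higher and lower genes depends on how the arrays are scaled.

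Of 10 measured fermentation genes 4 rose in FR13A, none fell and 6 did not pass the test. Adjusted over the list alone, 5 rose. Besides ADH2 and ALDH2A, ADH1 (Os11g0210300) rose by 3.58 ± 0.92 and PDC1 (Os05g0469600), a pyruvate decarboxylase, by 2.30 ± 0.62 at its brightest probe, the lowest of 4 probes that reached 8.62. ADH1 was saturated on 2 arrays of slide 1, where its log2 fold change was 1.86, against 4.91 and 3.97 on the other slides. With saturated spots left out the value of ADH1 was 4.34 (limma adjusted p = 0.000162). PDC2 (Os03g0293500) had a log2 fold change of 1.83 ± 0.72 (limma adjusted p = 0.0845, or 0.0331 with the replicate number as a block). It was saturated on 2 arrays, and with saturated spots left out its value was 2.35 (adjusted p = 0.00455). The set test of the list against all other genes by camera gave an adjusted p of 0.0133 with a preset correlation, and adjusted p = 0.341 with an estimated correlation. Of 5 measured gibberellin genes 4 rose, also when adjusted over the list alone. GA20ox2 (Os01g0883800), a gibberellin synthesis enzyme, rose by 4.72 ± 0.86. GID1 (Os05g0407500), the gibberellin receptor, rose by 2.26 ± 0.32. SLRL1 (Os01g0646300), a repressor of the gibberellin response, rose by 1.70 ± 0.50. GA2ox1 (Os05g0158600), an enzyme that inactivates gibberellins, was at least 13.6-fold higher, with no control array well above background. That bound holds for all arrays together. The log2 fold change of GA2ox1 was 3.66 to 4.97 with single arrays left out and 3.13 with normexp background correction. The set test gave adjusted p = 0.00963 with the preset correlation and adjusted p = 0.223 with an estimated correlation.

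Of 5 measured genes of sucrose and starch breakdown 3 rose in FR13A, the same number as when adjusted over the list alone. The protein kinase CIPK15 (Os11g0113700) rose by 4.54 ± 1.04, the sucrose synthase SUS1 (Os03g0401300) by 3.11 ± 0.54 (1.04 to 3.24 over its 7 kept probes) and SUS4 (Os03g0340500) by 1.74 ± 0.58. The set test of this list did not pass in FR13A (adjusted p = 0.0712). It gave adjusted p = 0.0266 with the replicate number as a block and adjusted p = 0.23 with an estimated correlation. Among 6 measured ethylene genes 2 rose, and 2 rose and 1 fell when adjusted over the list alone (set test adjusted p = 0.771). These were ACS1 (Os03g0727600), an enzyme of ethylene synthesis, by 4.12 ± 0.94 and EIL1 (Os03g0324200), a transcription factor of ethylene signalling, by 1.22 ± 0.37. ACS1 was well above background on 1 of 3 control arrays, and its other kept probe gave 1.61. The camera test asks for a shared direction. With fry for change in either direction, which compares with no other genes, the ethylene list gave adjusted p = 0.000334. Of the 2 ERF transcription factors, SUB1C (Os09g0286600) rose by 1.86 ± 0.33 and SUB1B (Os09g0287000) had a log2 fold change of 1.33 ± 0.84 (limma adjusted p = 0.276, or 0.0465 with the replicate number as a block). SUB1B was saturated on all 4 arrays of slide 1, where its log2 fold change was 0.26, against 1.68 and 2.04 on the other slides. With saturated spots left out it was 1.86 (adjusted p = 0.0534). SUB1A was not analysed here. The genes that fell included NiR (Os01g0357100), nitrite reductase, with a log2 fold change of -2.52 ± 0.34, SGR (Os09g0532000), which acts in chlorophyll breakdown, with -2.01 ± 0.46, OPR7 (Os08g0459600), a jasmonate synthesis enzyme, with -1.46 ± 0.24, and TPS1 (Os05g0518600), of trehalose metabolism, with -1.12 ± 0.34, which became 0.69 with normexp background correction. Each was the 1 gene called of its list, with 2 measured genes of nitrogen assimilation, 4 of chlorophyll breakdown, 2 of jasmonate and 1 of trehalose metabolism, and 1 gene in each list fell when adjusted over the list alone. None of the 6 measured circadian clock genes, the 3 abscisic acid genes, the 2 defence genes, the 3 reference genes or the single markers of meristem and vein was called, and none passed when adjusted over the list alone. The SE of the clock genes' fold changes reached 1.58, so this does not show that they were unchanged. Of 4 measured root markers none was called, and 1 rose and 1 fell when adjusted over the list alone. The reference gene ACT1 (Os03g0718100) had a log2 fold change of -0.44 ± 0.32, and HB1 (Os03g0233900), a haemoglobin, one of 0.64 ± 0.49. Without one or another array the calls of 6 of these genes were lost, with the highest limma adjusted p at 0.0717 for ADH1 (2.88 without FR13A submerged replicate 2), 0.0828 for PDC1, 0.109 for SLRL1, 0.129 for EIL1, 0.181 for SUS4 and 0.106 for TPS1. With normexp, whose estimate failed on FR13A submerged replicate 2, the calls of GA2ox1 (adjusted p = 0.0733), SLRL1 (0.0876), EIL1 (0.0975), SUS4 (0.138) and TPS1 were lost. Those of SUS4 (0.0692) and TPS1 (0.0718) were lost with saturated spots left out, and that of TPS1, by falling under 2-fold, with quantile normalization.

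In Goda Heenati the question was the same, and genes of fermentation, gibberellin and sucrose and starch breakdown were again among those that rose. ADH2 was at least 2200-fold higher, again with no control array well above background (8.84 on the log2 scale at its lowest probe), and ALDH2A rose by 6.03 ± 0.43 (limma adjusted p = 1.4e-05). In all 4681 genes were called, 2065 higher and 2616 lower, a balance that again depends on how the arrays are scaled. Of the 10 fermentation genes 6 rose and none fell, and 7 rose when adjusted over the list alone. ADH1 rose by 3.26 ± 0.92, LDH (Os02g0105400), a lactate dehydrogenase, by 2.27 ± 0.58, PDC1 by 2.12 ± 0.62 (the lowest of 4 probes that reached 6.91) and AlaAT1 (Os10g0390500), an alanine aminotransferase, by 1.01 ± 0.20. On slide 1, where ADH1 was saturated on 2 arrays, its value was 1.11, against 4.71 and 3.96 on the other slides. With saturated spots left out ADH1 rose by 4.25 (limma adjusted p = 0.000166). PDC2 had a log2 fold change of 2.12 ± 0.72 (limma adjusted p = 0.0547, or 0.0197 with the replicate number as a block), and 2.83 (adjusted p = 0.00175) with saturated spots left out. The set test gave adjusted p = 0.00116 with the preset correlation and adjusted p = 0.223 with an estimated correlation.

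Of the 5 gibberellin genes 3 rose in Goda Heenati, as they did when adjusted over the list alone. GA20ox2 rose by 4.51 ± 0.86, GID1 by 2.08 ± 0.32 and SLRL1 by 1.89 ± 0.50, and the set test gave adjusted p = 0.0174, or adjusted p = 0.223 with an estimated correlation. Of the 5 genes of sucrose and starch breakdown 3 rose, and 4 when adjusted over the list alone. CIPK15 rose by 4.50 ± 1.04, SUS1 by 4.27 ± 0.54 (1.28 to 4.37 over its 7 kept probes) and the alpha-amylase RAmy3D (Os08g0473900) by 2.99 ± 0.69. For RAmy3D and for ACS1, 1 of 3 control arrays was well above background. The set test gave adjusted p = 0.0255, or adjusted p = 0.223 with an estimated correlation. Of the 6 ethylene genes 2 rose and 2 fell. ACS1 rose by 4.96 ± 0.94 (2.44 at its other kept probe) and EIN2 (Os07g0155600), a component of ethylene signalling, 2.14-fold (limma adjusted p = 0.00515). The ethylene-forming enzyme ACO1 (Os09g0451400) fell by 3.58 ± 0.64. The camera test of the ethylene list, which asks for a shared direction, did not pass (adjusted p = 0.927). With fry for change in either direction the list gave adjusted p = 0.000787. Of its genes 3 rose and 2 fell when adjusted over the list alone. SUB1C rose by 2.18 ± 0.33, and SUB1B had a log2 fold change of 1.82 ± 0.84 (limma adjusted p = 0.141, or 0.0143 with the replicate number as a block), and 2.55 (adjusted p = 0.0192) with saturated spots left out. PR1B (Os01g0382000), a pathogenesis-related protein, rose by 2.66 ± 0.79, PAO (Os03g0146400), which acts in chlorophyll breakdown, by 1.30 ± 0.37 and PT11 (Os01g0657100), on the root marker list, by 2.52 ± 0.54. PT11 was the only gene called of 4 measured root markers, whose median log2 fold change was -1.25. Adjusted over that list alone, 1 rose and 1 fell. NiR had a log2 fold change of -1.41 ± 0.34 and OPR7 one of -1.16 ± 0.24, both called as lower. None of the 6 clock genes was called, with an SE of up to 1.58, which does not show that they were unchanged. Without one or another array the calls of 7 of these genes were lost on the adjusted p, with the highest at 0.0984 for ADH1, 0.0898 for PDC1, 0.0644 for LDH, 0.0751 for SLRL1, 0.0529 for NiR, 0.116 for PR1B and 0.0981 for PAO (limma). Those of EIN2, AlaAT1 and OPR7 were lost in some by falling under 2-fold, as were EIN2 and AlaAT1 with quantile normalization. With normexp the calls of AlaAT1 (under 2-fold), ADH1 (limma adjusted p = 0.051), PDC1 (0.0746), PR1B (0.0768, and 0.0603 with saturated spots left out), ACO1 (0.0874), PAO (0.106), PT11 (0.199), RAmy3D (0.244) and SLRL1 (0.285) were lost. The failed normexp estimate on FR13A submerged replicate 2 enters these p-values through the shared estimate of spread. Its part in these losses was not separated from that of the background correction.

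**Figure D1:**
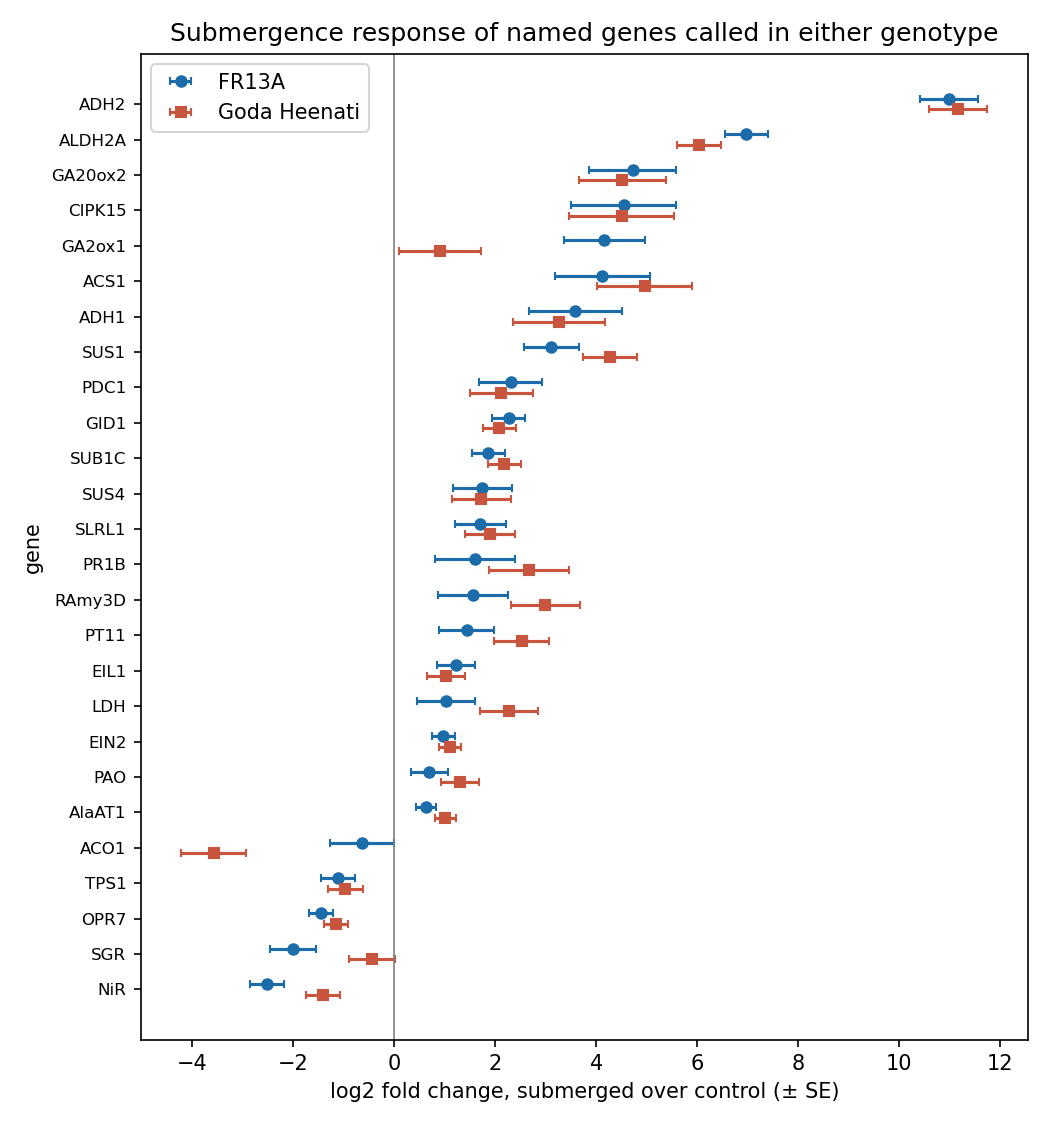
Log2 fold change of submerged over control leaves (horizontal axis, with the standard error as bars) for the genes named in the text that were called in at least 1 genotype, with FR13A as circles and Goda Heenati as squares, 3 arrays per group. The largest values are those of ADH2, 10.98 in FR13A and 11.16 in Goda Heenati, which rest on control arrays that were not well above background.

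Whether the genotypes responded differently was asked next, and for most genes no difference was called. The responses called 1410 genes higher in both genotypes and 1963 lower in both, where independent lists would share 206.6 and 308.5, and 6 genes were called in opposite directions. The log2 fold changes of the 2 responses, which share no arrays, correlated across 22744 genes with Pearson's r = 0.881 and Spearman's rho = 0.85. Within slides the correlation was 0.869, 0.795 and 0.843. Although 2880 genes were called in 1 genotype and not in the other, the test of the difference itself called 21 genes, 9 with a higher and 12 with a lower response in FR13A. With the replicate number as a block it called 83 genes, including those 21. Without FR13A control replicate 1 it called 7 genes, and without Goda Heenati submerged replicate 3 it called 45. None of the named genes was among the 21. ACO1, with a log2 fold change of -0.64 ± 0.64 in FR13A and -3.58 ± 0.64 in Goda Heenati, had a difference of 2.94 ± 0.91 that did not pass (limma adjusted p = 0.536). In FR13A ACO1 was well above background on 2 of 3 control and 1 of 3 submerged arrays, so a fall there could hardly be measured. GA2ox1 had a difference of 3.27 ± 1.14 that did not pass either (limma adjusted p = 0.746). On slides 1, 2 and 3 the difference was 4.48, 2.99 and 1.35 for ACO1 and 3.1, 2.62 and 4.07 for GA2ox1. Both tests were made without a block. Whether the 83 genes called with the replicate number as a block include named genes was not examined. Only in submerged FR13A was any array well above background for GA2ox1, so the size of its difference rests on dim signal. Of the 21 genes, 5 were well above background on all 12 arrays.

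The genotypes were then compared directly, in each treatment. In controls 1921 genes were called, 937 higher and 984 lower in FR13A, and under submergence 2311 were called, 1122 higher and 1189 lower. The recorded distance from tip to water surface was 52.7 ± 2.3 cm for submerged FR13A and 45.9 ± 2.9 cm for submerged Goda Heenati. Depth and genotype are therefore not separated under submergence, nor in the difference between the responses. The 2 comparisons shared 722 higher and 779 lower genes, against 46.22 and 51.44 for independent lists, and no gene was called in opposite directions. Few of the named genes were among them. ACO1 was lower in FR13A in controls, with a log2 difference of -5.46 ± 0.64 (limma adjusted p = 0.000206), and under submergence, with -2.52 ± 0.64 (adjusted p = 0.0281). The difference under submergence became 0.22 with normexp background correction, whose estimate failed on FR13A submerged replicate 2. ACO1 was well above background on 2 of 3 control and 1 of 3 submerged FR13A arrays. Under submergence, AOS2 (Os03g0225900), a jasmonate synthesis enzyme, differed by -3.12 ± 0.82, PDC4 (Os01g0160100) by -1.17 ± 0.33 and ALDH2A by 1.52 ± 0.43. GA2ox1 was at least 5.2-fold higher in submerged FR13A leaves than in submerged Goda Heenati leaves, where no array was well above background. That bound holds for all arrays together, and leaving out single arrays moved the log2 difference between 2.03 and 3.79. No gene list passed the set test by camera in either genotype comparison or for the difference between the responses. With fry, which asks whether the genes of a list move one way and compares them with no other genes, the ethylene list passed in controls (adjusted p = 0.0245), with 1 of its 6 genes called. Without one or another array all 5 calls under submergence were lost, with the highest limma adjusted p at 0.115 for ACO1, 0.136 for AOS2, 0.169 for PDC4, 0.167 for ALDH2A and 0.142 for GA2ox1. They were also lost with normexp, with an adjusted p of 0.0918 for ALDH2A, 0.137 for AOS2, 0.362 for GA2ox1, 0.465 for PDC4 and 0.933 for ACO1, and some with quantile normalization (0.0523 for ALDH2A) or with saturated spots left out (0.0583 for GA2ox1 and 0.0974 for PDC4).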

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

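The 4 loci below, picked as the largest differences in each direction, the tests of them under other processing and the look at regroupings that move equal numbers of labels were chosen after the results were seen, and the other tests were set before. Among the 5 genes called for the difference between the responses and well above background on all 12 arrays, Os01g0778600 had a difference of 3.85 ± 0.48 (limma adjusted p = 0.0182), with a log2 fold change of 3.51 in FR13A and -0.34 in Goda Heenati. Os06g0180800 had a difference of 2.05 ± 0.29 (adjusted p = 0.0389), with -0.50 and -2.55. Os12g0202700 had a difference of -5.18 ± 0.56 (adjusted p = 0.00935), with -4.28 in FR13A and 0.90 in Goda Heenati. Os07g0421900 had a difference of -4.94 ± 0.71 (adjusted p = 0.0397), with -2.09 and 2.85. In all 4 the 3 slides gave the same sign. This is no separate support, since the loci were picked for large called differences on these same arrays. All 4 were called with quantile normalization. With probes well above background on all 12 arrays only Os12g0202700 was called (adjusted p = 0.0347), and with saturated spots left out Os12g0202700 (0.0441) and Os01g0778600 (0.0325). None of the 4 was called with normexp (lowest adjusted p 0.463) or without slide 1 (lowest 0.246, limma). Without slide 1 the differences were 3.49 for Os01g0778600, 2.21 for Os06g0180800, -5.3 for Os12g0202700 and -5.6 for Os07g0421900. A test of the difference itself singled them out, and no gene name was established for them. Of the 21 genes called, 15 had a group with no array well above background.

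The small number of genes called for the difference, 21, was set against an explanation named before the blocked fit was made, that differences between slides widen the spread. With the slide, which is also the replicate number, as a block 83 genes were called, which is consistent with that explanation for part of the count, though a batch shared by a replicate number would act alike. A real similarity of the responses stays open and was not tested separately. At an unadjusted p under 0.05 there were 1023 genes (limma).

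In 6 of 100 regroupings of the genotype labels within treatments, drawn from 200 and with the real one included, at least 21 genes were called for the difference, so this count does not exclude chance. It is a poor test of chance here, because all 5 other such regroupings moved unequal numbers of labels in the treatments, which lets the difference between genotypes into the contrast. The highest, with 3410 genes, exchanged all genotype labels in the controls alone. The 48 other regroupings that moved equal numbers called at most 1 gene. They mix the genotypes within each group, which widens the spread and lowers the count, so they do not decide on chance either.

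The correlation of the 2 responses could come in part from slide effects shared by both. An effect that was the same on all arrays of a slide cancels in each response, since every slide held submerged and control arrays of both genotypes. Only a slide effect that differed between the treatments could remain. Responses measured on different slides correlated with r of at least 0.626, against at least 0.795 on the same slide. That falls between the bounds set beforehand. A slide effect that differed between the treatments and a shared response therefore cannot be told apart for part of the correlation.

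Genes called between the genotypes in controls might reflect sequence variants under single probes. Among 313 such genes with another kept probe, the other probes showed a median share of 0.99 of the called probe's fold, and 94.6% had its sign. Relative to the same share for the FR13A submergence comparison the value was 0.99, which argues against variants under single probes as the whole cause for genes with several probes. A median does not show whether variants account for a minority of these genes. The choice of the brightest probe also makes a probe dimmed by a variant less likely to stand for its gene. Genes with 1 kept probe, such as ACO1, and differences that touch every probe of a gene such as a missing copy, stay open.

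For the 4 comparisons of a pair of groups, the 6 arrays make 10 splits, too few for a share under 0.05. The real split was the 1 split with as many called genes in each. It called 4957 genes for FR13A submerged against control, 4681 for Goda Heenati, 1921 between genotypes in controls and 2311 between genotypes under submergence, and the highest other splits called 0, 0, 0 and 4 genes. Every other split mixes both groups, which widens the spread and lowers its count, so these counts do not measure chance.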

How the results depend on the processing

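Tests with saturated spots left out, slide 1 left out, and normexp with 1 array left out were chosen after seeing the data. The main fit held no block. With the replicate block (pairing by number, which is also the slide) the difference between the responses called 83 genes in place of 21. The other counts rose as well, to 6424 for submergence in FR13A and 6099 in Goda Heenati. Between the genotypes they rose to 2430 in controls and 2936 under submergence. The set test of sucrose and starch breakdown in FR13A passed with it (adjusted p = 0.0266, 0.00151 to 0.23 over alternatives). So did PDC2 and SUB1B in both genotypes. All 46 called gene values held. Not all uncalled ones were tested. The difference called 44 genes with quantile normalization, 54 with normexp and quantile, 48 with the authors' value table, 36 with the scan day as a block, 76 with array weights, 6 at an adjusted p under 0.01, 12 without saturated spots, 1 with probes well above background on all 12 arrays (limma) and 0 without slide 1 (limma; 1023 at an unadjusted p under 0.05 with all slides). The filter on all 12 arrays gave 754 genes between genotypes in controls and 995 under submergence. At an adjusted p under 0.01 the submergence counts were 2972 in FR13A and 2809 in Goda Heenati, and without slide 1, 2546 and 2631.

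With normexp the counts were 1864 in FR13A, 1909 in Goda Heenati, 0 for the difference, 550 between genotypes in controls and 614 under submergence (limma). The share of higher calls went from 45.9% to 72.9%, from 44.1% to 57%, and between genotypes from 48.8% to 70.2% and from 48.6% to 87.3%. The median log2 fold change of all genes, 0.049 in FR13A and 0.09 in Goda Heenati, was 0.566 and 0.167 with normexp and 0.199 and 0.216 with median scaling. Such a shift moves the balance between higher and lower calls. The normexp estimate failed on FR13A submerged replicate 2, with a background mean of -2522 where the measured median was 23, and the means were -132 and -139 on replicate 1 of submerged FR13A and Goda Heenati (25.5 and 26 measured). With the first array left out, which does not remove the others, the counts were 2846 in FR13A, 7 for the difference and 1295 between submerged genotypes. Only counts that still lay far from the main ones are given. FR13A submerged replicate 2 also enters the normexp tests of Goda Heenati and of the controls, through the shared estimate of spread. Of 46 called values of named genes, 27 kept their call with normexp, 42 with quantile normalization and 40 with saturated spots left out. Under normexp 3 values changed sign, TPS1 in FR13A (0.69), ACO1 between submerged genotypes (0.22) and RAB16A in FR13A (0.24). With an estimated correlation 0 gene list tests passed in place of 5, and 7 passed with fry. The cause of the other changes was not tested.

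Leaving out each array in turn gave 7 (without FR13A control replicate 1) to 45 genes (without Goda Heenati submerged replicate 3) for the difference. Of the 46 called values, 24 kept their call in every leave-out and 22 lost it in some. ADH2, ALDH2A, SUS1, CIPK15, GA20ox2, GID1, ACS1 and SUB1C kept it in both submergence comparisons. Signal near background limits the genes with a dim group.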
